A study of Mus musculus with 40 samples.

How the data were processed

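Liver lobes of DARLIN mice were sampled, and 1 of 40 libraries in the series, the right inferior lobe of animal YK184 marked E15.5, was analysed here. Per the labels' protocols, total RNA was extracted, reverse transcribed with an array-specific primer carrying a UMI, amplified by nested PCR for the array at Col1a1, indexed and sequenced on a NextSeq 1000. The genome build mm10 is named per the submitters' processing notes. The program that aligned reads and called alleles, its settings and its filters on reads or UMIs are not given in the sources used here, so how much these removed is unknown.

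The authors deposited 2 text lists for this library, with no header. One gives, for each distinct allele, its edits as deletions, insertions, deletions with inserted bases and substitutions at positions along the array. The other gives, in the same order, the 12-base UMIs of each allele. Neither holds deposited counts, normalized values or read numbers. UMIs per allele were counted from the list. All 32342 UMIs were listed under 1 allele each. The read depth is unknown, and the number of UMIs sets the precision.

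Positions were placed on the array as 10 targets of 20 bases in a repeat unit of 27 bases. This layout was taken from general knowledge of the array, since no array sequence was among the sources used here. It was checked on the data: all 291 listed substitutions stated the base that the layout has at that position, against 25% expected for random bases. These substitutions lay at 40 positions, among them 18 of the 30 bases that end the targets. A site counted as altered when an event touched the last 7 bases of its target, the window around the cut. A deletion joined sites when it touched the windows of 2 or more. A remaining array was rebuilt by applying all events of an allele. The coordinates of Col1a1 come from the annotation of GRCm38.p6, the assembly that mm10 names.

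Shares over alleles have exact binomial (Clopper-Pearson) 95% intervals. The share of the 10 largest alleles and the effective number have SDs from 1000 multinomial resamples of UMIs. Medians and base shares have bootstrap intervals from 1000 resamples of alleles. The extent of sampling was described with Good's coverage, from alleles with 1 UMI, and the Chao1 lower bound, from alleles with 1 and 2 UMIs. The difference in log2 UMIs and the rank correlation were tested across alleles with two-sided permutation tests of 100000 resamples, adjusted over these 2 tests by Benjamini-Hochberg. All intervals and tests treat the listed alleles or UMIs as independent draws within 1 library. They do not cover the change of a value with the number of UMIs sampled. No groups were compared, since 1 sample was analysed.

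A rule for naming alleles and sites was fixed before the data were examined. It named the 10 alleles with the most UMIs, all 10 target sites, the 5 site pairs most often joined over alleles, and Col1a1. It also named the alleles with the longest deletion and the longest insertion among those with at least 3 UMIs. Other alleles and site pairs were named outside this rule. Among them were the pair of the outermost sites and the deletion exactly between their cuts. The most abundant allele with a reverse-complement stretch, and site pairs given for such stretches and for exact cut-to-cut deletions, were also outside it. Inserted sequences longer than 3 bases were not printed, since their origin was not established.

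Alternatives fixed before the data were examined were minimums of 2, 3 and 5 UMIs per allele, collapsing UMIs 1 base apart within an allele, leaving out UMIs listed under several alleles, folding alleles that differ by 1 inserted base into the larger, leaving out the largest allele, a random 50% of UMIs, weighting alleles by UMIs, the whole target in place of the cut window, alleles with a single event, substitutions counted as unedited, and Pearson's r. Added after seeing the data were leaving out events outside the cut windows, leaving out alleles that hold a reverse-complement stretch of 20 or more bases, and insertions alone.

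The scripts were tested on simulated data. Altered sites, rebuilt sequences and edit classes were recovered for 100% of 2000 simulated alleles. An inverted stretch of 1 unit was found in 100% of 500 simulated alleles, with both ends within 3 bases of the true cut in 98.4%, and in 0 of 500 alleles with random insertions. In simulated libraries with no effect, the difference test called 4% and the correlation test 6% of 200 repeats at a threshold of 0.05. With a log2 difference of 0.5 the difference test called 86%. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used, with the random seed 7.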

Results

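The series traced cell lineages in mouse liver with DARLIN, a mouse line that carries transgenic arrays of Cas9 target sites. The array amplified here is the one at the Col1a1 locus, with 10 target sites. In DARLIN mice, Cas9 is fused to terminal deoxynucleotidyl transferase (TdT), an enzyme that adds bases to DNA ends without a template. A cell whose array is cut keeps the resulting sequence change, and its descendants inherit it, so cells that share an edited array (an allele) can share an ancestor. Col1a1 encodes a chain of type I collagen and spans bases 94936224 to 94953042 of chromosome 11 in GRCm38.p6. Where within or beside the gene the array lies is not given in the sources used here.

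The labels describe 40 liver samples from 5 animals, in 18 groups of stage mark and lobe. Of these, 16 samples carry the mark E15.5, 14 the mark E10 and 10 the mark E12. The labels do not say whether the mark is the time of induction or of collection. Files were analysed for 1 sample, the right inferior lobe of animal YK184, marked E15.5. Its group holds 2 samples, and the other one was not analysed here. No comparison between stages, lobes or animals was therefore made, and there are no replicates. Every interval given treats the listed alleles or UMIs as independent draws within this library. It does not cover the change of a value with the number of UMIs sampled. A unique molecular identifier (UMI) tags 1 array transcript at reverse transcription, so UMIs count RNA molecules and not cells.

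The list for this lobe held a very diverse set of edited arrays. The library listed 12767 alleles carried by 32342 UMIs, and every listed allele was edited. The unedited array was not listed. Whether the files list every molecule is not given in the sources used here, so no upper limit on its share was set. Most alleles were rare. Of the 12767 alleles, 8059 had 1 UMI (63.1%, 95% exact binomial interval 62.3 to 64.0%), 2266 had 2 UMIs and 2442 had 3 or more. At the other end, 301 alleles with 10 or more UMIs held 32.2% of all UMIs, and 12 alleles had 100 or more. The 1323 most abundant alleles held 50% of the UMIs.

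**Figure D1:**
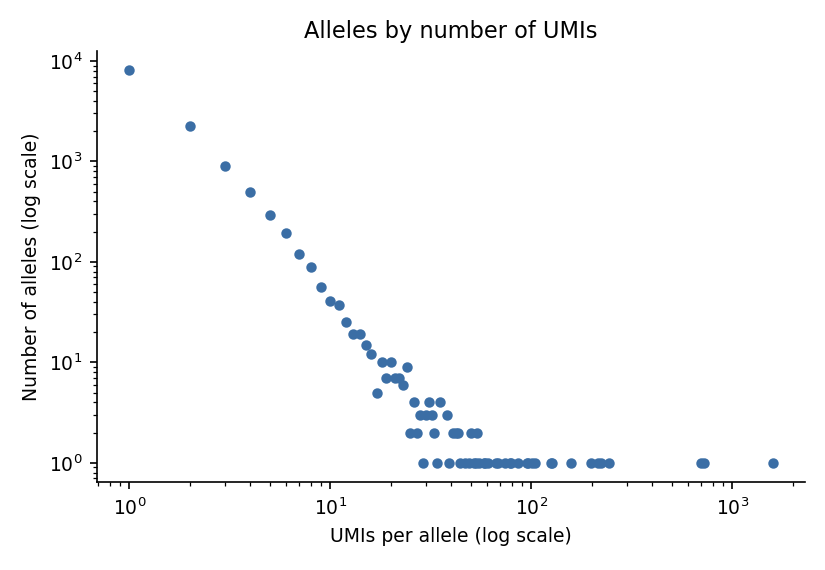
Number of alleles (vertical axis, log scale) against UMIs per allele (horizontal axis, log scale) in the E15.5 right inferior lobe library; each point is 1 UMI number. Counts fall from 8059 alleles with 1 UMI to a single allele with 1589 UMIs.

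The 10 largest alleles held 13.3% of UMIs (resampling SD 0.187, 1000 multinomial resamples). The effective number of alleles, the exponential of the Shannon entropy, was 4305 (resampling SD 41.1). Sampling was incomplete. Good's coverage was 75.1%, and the Chao1 lower bound was 27090 alleles, of which the listed alleles are 47.1%. A random draw of 50% of the UMIs kept 7951 alleles, with an effective number of 3259. The effective number thus depends on the number of UMIs far more than its resampling SD shows. Counting only alleles with at least 2, 3 or 5 UMIs left 4708, 2442 or 1051 alleles, with effective numbers of 1655, 852 and 359. At 3 and 5 UMIs the 10 largest alleles held 21.8% and 28.5% of the UMIs.

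The 7 most abundant alleles each lost nearly the whole array between target sites 1 and 10 in a single event, with or without inserted bases. Positions are counted from 1 at the first base of the array. The largest allele, a deletion of bases 23 to 268, had 1589 UMIs (4.91% of UMIs, 95% exact interval 4.68 to 5.15%). The second lacked bases 23 to 264 and had 727 UMIs (2.25%), and the third lacked bases 23 to 265 with an inserted G and had 698 UMIs (2.16%). A deletion of bases 24 to 265 had 244 UMIs and one of bases 23 to 263 had 199 UMIs. The deletion of bases 23 to 265 also occurred with T (222 UMIs) and with AG (215 UMIs) inserted, and that of bases 23 to 264 with A inserted (126 UMIs). Only 2 of the 10 largest alleles held separate events. In the first, GG was inserted after base 22 and bases 50 to 263 were deleted (157 UMIs). In the second, bases 23 to 238 were deleted and GG was inserted after base 265 (127 UMIs). Identical edits made in different cells share an allele, so an allele is not necessarily 1 clone.

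Most alleles, in contrast, combined several events. The 12767 alleles carried 42668 events, with a median of 3 and a maximum of 10 per allele. Alleles with 2 or more events made up 96.6% of alleles and 80.6% of UMIs. A single deletion joining sites formed 131 alleles but 11.6% of UMIs, and a single deletion with inserted bases formed 300 alleles and 7.81% of UMIs. No allele consisted of 1 insertion, 1 deletion within a site or substitutions alone. Such arrays would be longer than nearly all of those listed, so no upper limit on their share was set. By kind, 15632 events were insertions, 13856 deletions, 12889 deletions with inserted bases and 291 substitutions.

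Deletions joining 2 or more target sites were present in 12766 of 12767 alleles (99.99%, 95% exact interval 99.96 to 99.9998%). All 45 pairs of sites were joined in at least 1 allele. The 5 pairs most often joined over alleles were sites 1 and 8 (1084 alleles, 8.49%), 3 and 10 (1049 alleles, 8.22%), 1 and 9 (1023 alleles, 8.01%), 1 and 3 (982 alleles, 7.69%) and 8 and 10 (900 alleles, 7.05%). The exact intervals of the first 4 pairs overlapped, and their order was not tested. Sites 1 and 10 were joined in fewer alleles but in 5890 UMIs, more than any other pair; this pair was added after its values were seen. The median deletion over all 26745 deletions was 73 bases (95% bootstrap interval 69 to 78), and 126 bases among alleles with at least 5 UMIs. The longest deletion in an allele with at least 3 UMIs removed bases 7 to 265, with 19 bases inserted, in 5 UMIs.

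Most listed deletions started, and most ended, near a predicted Cas9 cut, and most insertions lay at one. Of deletions, 77.3% started and 75.8% ended within 3 bases of a cut, and 88.1% of insertions lay exactly at one. Of the listed substitutions, 100% lay inside a cut window. Whether the allele caller kept or placed edits at expected cuts is unknown, and no share expected by chance was computed. These shares are therefore no independent check of the cut positions. Deletion starts were most frequent at base 23 (5793 events), directly after the cut of site 1, and deletion ends at base 265 (3483 events), directly before that of site 10.

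**Figure D2:**
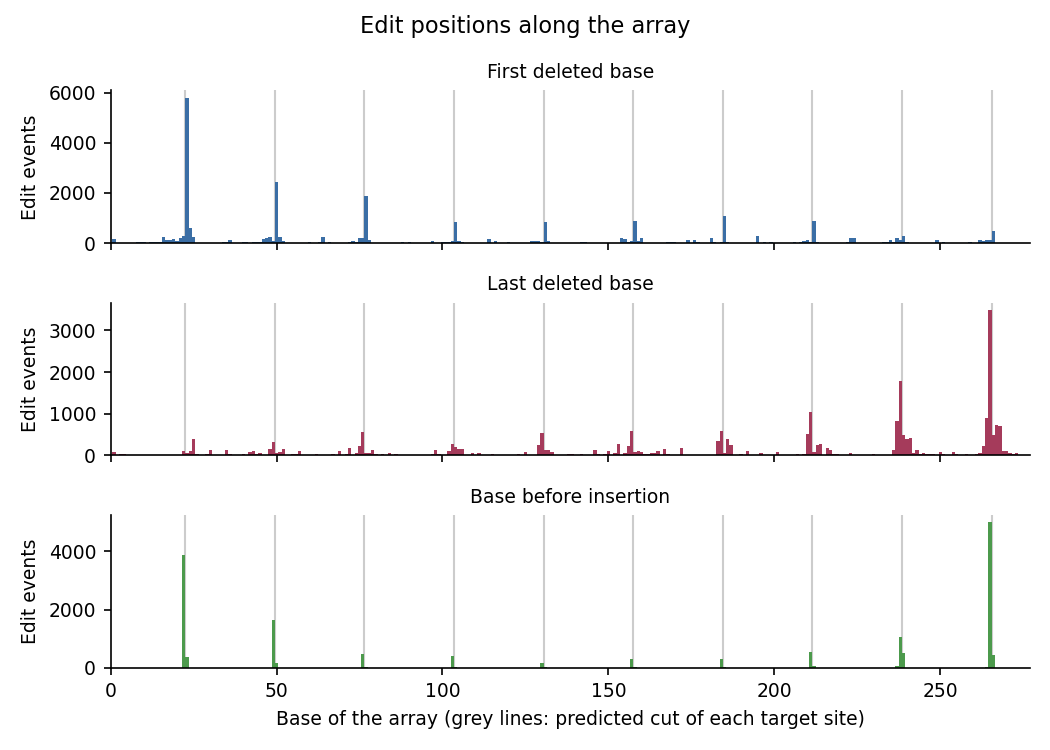
Number of edit events (vertical axes) at each base of the array (horizontal axis) for the first deleted base, the last deleted base and the base before an insertion, with grey lines at the predicted cuts. The highest bars are 5793 deletion starts at base 23, 3483 deletion ends at base 265 and 4987 insertions after base 265.

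Editing reached all 10 target sites. In 88.9% of alleles (95% exact interval 88.4 to 89.4%) every site was altered, with 9.84 altered sites per allele on average and at least 3 in every allele. Site 3 was altered in 99.5% of alleles (99.4 to 99.6%) and site 9 in 96.0% (95.7 to 96.4%), the highest and lowest shares over all alleles; the interval of site 3 overlapped that of site 7. The order depended on which alleles were counted: site 10 had the lowest share at 3 or more UMIs (97.75% against 97.91% at site 9), at 5 or more UMIs (97.53% against 98.19%) and in alleles with a single event (75.2% against 89.6%). The highest share was at site 5 at 3 or more UMIs, at sites 3, 5, 6 and 7 alike at 5 or more UMIs, and at sites 6 and 7 in alleles with a single event. Sites 1, 2 and 10 were altered in 97.8%, 97.9% and 97.8%, site 4 in 98.6%, site 5 in 99.2%, site 6 in 99.1%, site 7 in 99.3% and site 8 in 98.6%. Averaged over sites, the share was 98.4%. The middle of the array was mostly lost within multi-site deletions, which took site 5 in 94.2% of alleles. The outer sites were often edited on their own. Site 10 was within a multi-site deletion in 44.6% and altered alone in 53.2% of alleles, and site 1 in 52.9% and 44.9%. The altered shares above count sites lost within multi-site deletions, so their order is not an order of editing at the sites themselves. Among alleles in which the site was outside such a deletion, site 10 was altered in 96.0% and site 1 in 95.3%, the highest shares. The lowest were 81.5% at site 4 and 83.0% at site 9.

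**Figure D3:**
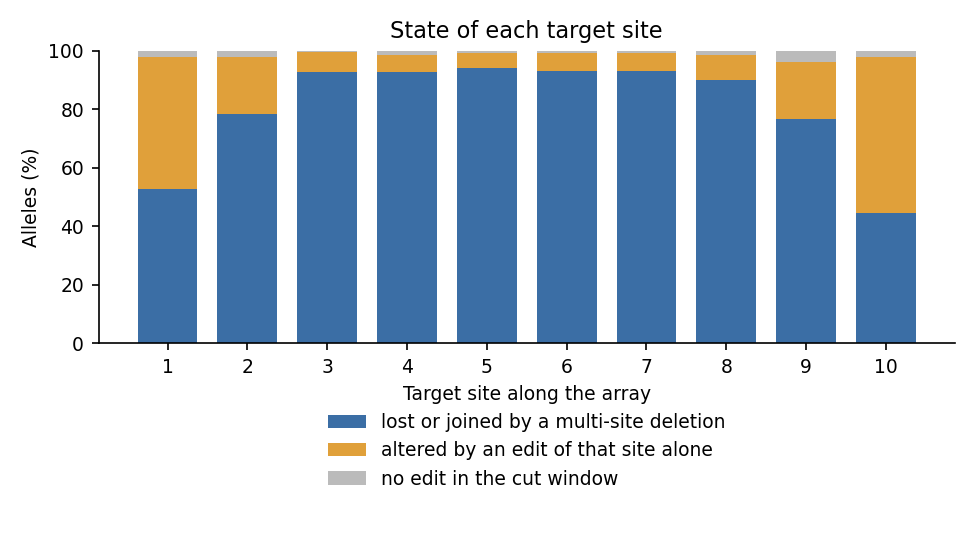
Percent of the 12767 alleles (vertical axis) in which each target site (horizontal axis) was part of a multi-site deletion, altered by an edit of that site alone, or without an edit in its cut window. Multi-site deletions took 94.2% at site 5 and 44.6% at site 10.

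The arrays left after editing were short, with a median of 91 bases (quartiles 70 and 117) and a range of 26 to 227. Weighted by UMIs the median was 71 bases. Lengths clustered in steps of about the 27-base repeat unit, and the number of alleles fell 15.1-fold from 256 alleles of 170 to 179 bases to 17 alleles of 180 to 189 bases. Lightly edited arrays, which would be longer, were thus nearly absent, and the shares for joined and altered sites above describe arrays mostly under that length.

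**Figure D4:**
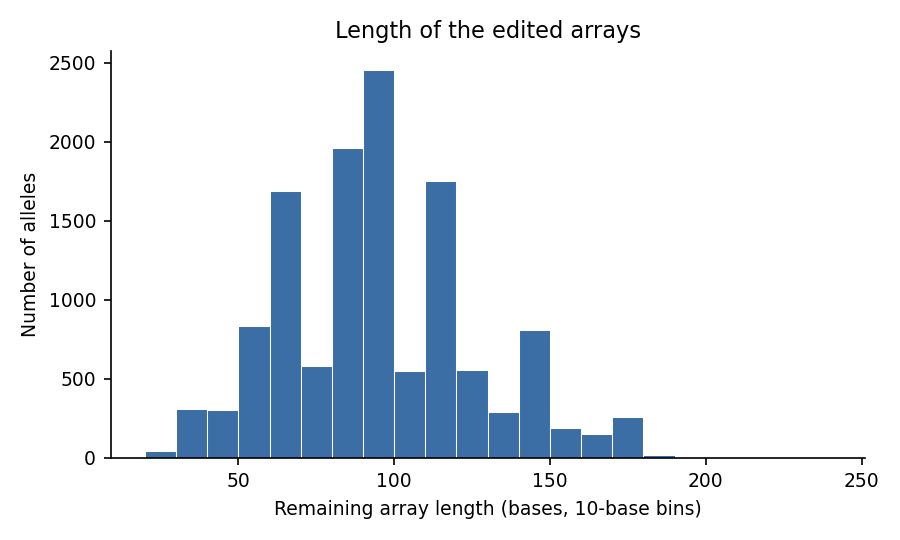
Number of alleles (vertical axis) by remaining array length in bases (horizontal axis, bins of 10 bases). The highest bin, 90 to 99 bases, holds 2454 alleles, and 17 alleles have 180 to 189 bases.

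Added bases were found in nearly all alleles. Of the 12767 alleles, 11899 carried an insertion or a deletion with inserted bases (93.2%, 95% exact interval 92.8 to 93.6%). Over all 28521 such events the median number of inserted bases was 2, and for insertions alone, a definition chosen after seeing the data, it was 1. Of insertions, 95.2% had 1 to 3 bases. The inserted bases of both kinds were 53.3% G or C (95% bootstrap interval 53.01 to 53.64%). In insertions, purines prevailed. G made up 42.1%, A 38.8%, T 10.7% and C 8.36% of the inserted bases, so that 81.0% were A or G (80.3 to 81.6%). This share ran from 71.4% at site 6 to 84.0% at site 3. The commonest insertions were G (19.9% of insertions), A (18.3%), GG (9.06%) and AG (6.92%). In deletions with inserted bases, A and G made up 50.8% of the inserted bases, and 69.1% where 1 to 3 bases were inserted. Of all alleles, 8.19% held a stretch of 20 or more bases equal to the array's reverse complement, which the list gives as several events with inserted bases. The longest inserted stretch in an allele with at least 3 UMIs had 35 bases, in a deletion of bases 73 to 85 in an allele with 6 events and 4 UMIs. It shared at most 7 consecutive bases with the array and 6 with its reverse complement.

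Alleles with added bases were rarer in UMIs than alleles without. Those with inserted bases had 2.20 UMIs on average (n = 11899 alleles) and those without had 7.07 (n = 868 alleles), with medians of 1 and 2. Mean log2 UMIs were 0.58 and 1.11, a difference of -0.53 (two-sided permutation test with 100000 resamples, p = 1e-05, Benjamini-Hochberg adjusted p = 1e-05 over 2 tests, the smallest these permutations can give). UMIs per allele also fell with the number of events. Alleles with 1 event had 14.6 UMIs on average, those with 2 events 3.37 and those with 3 events 2.003. The medians were 2, 2 and 1 UMIs, so the mean at 1 event rests on a few very large alleles. Spearman's rho across alleles was -0.26 and Pearson's r on log2 UMIs was -0.26 (each permutation p = 1e-05, the smallest possible; adjusted p for rho 1e-05). UMIs also differed by remaining length: 309 alleles of 30 to 39 bases held 5754 UMIs, and 2454 alleles of 90 to 99 bases held 4519. Neither test accounted for remaining length or for identical edits made in different cells. Neither separated inserted bases from the number of events. Alleles of 1 library are not independent replicates of a condition, and these p-values describe this library only.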

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

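Of the tests of the first signal below, the placement of run ends and the backward control were chosen after the runs had been seen, and the comparison by UMI number before its result.

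Stretches equal to the array's reverse complement were present in 1046 alleles (8.19% of alleles, 95% exact interval 7.72 to 8.68%), which held 1737 UMIs. Each of these stretches, or runs, had 20 or more consecutive bases. The run had a median of 27 bases, the length of 1 repeat unit, and a maximum of 66. Most lay between neighbouring cuts: in 166 alleles the run lay between the cuts of sites 6 and 7, in 139 between 5 and 6, in 117 between 1 and 2, and in 115 between 3 and 4. The most abundant such allele had 35 UMIs and a run that matched bases 50 to 76. In the deposited lists such a stretch appeared as several events, and alleles with a run had a median of 5 events against 3 in the others.

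Chance resemblance was argued against by the array read backwards without complementing, which gave such runs in 0 alleles; the array and its own reverse complement share at most 10 consecutive bases. A candidate explanation is inversion of a segment between 2 Cas9 cuts. In 76.7% of the alleles both ends of the run lay within 3 bases of a cut, against 18.0% for runs placed at random (95% range 15.6 to 20.3% over 1000 placements). Molecules joined during PCR stayed open. Runs were present in 4.66% of alleles with 5 or more UMIs (3.47 to 6.12%) and in 9.28% of those with 1 UMI. The bound written beforehand for excluding joined molecules came to 4.64% and did not mention the interval. The value met it narrowly, but its interval spans it, so no conclusion was drawn. Alleles with a run also had more events (median 5 against 3), and UMIs fell with the number of events. The comparison by UMI number cannot separate these. No explanation resting on stage, lobe or animal was tested, since 1 library gives no groups.

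UMIs that differ by 1 base from a UMI of another allele formed 1788 pairs, against 1621 ± 45.4 (SD, 20 shuffles) when bases were shuffled between UMIs at each position. Within alleles there were 7 such pairs, against 5.35 in the shuffles. Edits that started in the first 4 bases of the array and touched no cut window occurred in 179 alleles with 183 UMIs, and 98.9% of these alleles had 1 UMI.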

How the results depend on the processing

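Over 16 alternative settings, 86 of the 139 values for the 13 main results lay within the interval, count range or call of the reported value and 53 did not; for the 10 single sites, 76 of 130 did and 54 did not. These counts include values that could not differ or could hardly differ. They come from the settings named below as telling nothing about stability, and from the share of edited UMIs, which is 100% where no unedited array is listed. Both association tests kept their sign and an adjusted p of 1e-05 in every setting run. Alternatives added after seeing the data were leaving out events outside cut windows, leaving out alleles with a reverse-complement run, and insertions alone.

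Minimums of 2, 3 and 5 UMIs per allele gave 4708, 2442 and 1051 alleles, effective numbers of 1655, 852 and 359, 17.7%, 21.8% and 28.5% of UMIs in the 10 largest alleles, 90.5%, 87.6% and 83.1% of alleles with an insertion, 100% with a joining deletion at each minimum, median deletions of 87, 108 and 126 bases, and mean altered shares of 98.9%, 99.1% and 99.2%; G and C among inserted bases were 54.1% at 3 and 55.6% at 5 UMIs. By construction no allele with 1 UMI was left there, so that share had no value. Folding 911 alleles that differ by 1 inserted base into larger ones gave 64.2% with 1 UMI, 15.3% in the 10 largest, an effective number of 3439, 92.7% with an insertion and a median deletion of 61 bases. Without the largest allele the 10 largest held 9.17% and the effective number was 5398. A random 50% of UMIs gave 7951 alleles, 70.4% with 1 UMI, an effective number of 3259, 92.5% with an insertion, 100% with a joining deletion, a median deletion of 80 bases and a mean altered share of 98.5%. Weighting by UMIs gave 81.0% with an insertion, a median deletion of 108 bases, 54.1% G and C and a mean altered share of 99.0%; that share was 98.7% with the whole 20-base target and 91.5% for alleles with a single event. Without alleles holding a reverse-complement run, the 10 largest held 14.1%, the effective number was 3802, 92.6% had an insertion, 100% a joining deletion, the median deletion was 84 bases, 50.3% of inserted bases were G or C and the mean altered share was 98.3%. Leaving out events outside cut windows gave a median deletion of 80 bases. Insertions alone gave a median of 1 base and 50.5% G and C. Fewer alleles or UMIs follow from the construction of the minimums and of the random draw. The higher share of the 10 largest alleles and the lower effective number follow from the construction of the minimums and of the folding. For the other values the cause was not tested.

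Collapsing UMIs 1 base apart removed 7 UMIs, and leaving out UMIs listed under several alleles or counting substitutions as unedited changed nothing, since 0 such alleles or UMIs were listed; these settings say nothing about stability. The random draw kept fewer alleles, as it must where many alleles have 1 UMI. It cannot show whether depth or errors among those alleles set the allele number. Of UMIs, 24.9% belonged to alleles with 1 UMI. The effect of the authors' own filters is unknown. No paired analysis was possible because files of only 1 library were analysed.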

Other observations

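In this part, the bases by position in insertions, the comparison of long inserts with shuffled ones, the runs by event number, the share of UMIs with 1 or 2 altered sites, the 27-base windows of remaining length, the reassignment of target ends among sites and the slopes without the largest or the exact cut-to-cut product were chosen after seeing the data. The bound on the fall in length, the test of target ends over site pairs and the slope on shared bases were written down before their results.

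Among insertions of several bases, the listed composition differed between the first and the last inserted base. In 416 insertions of 4 bases, A rose from 33.4% at the first base to 76.4% at the last, while G went from 56.7% to 13.5%. In 1277 insertions of 3 bases, A was 30.1% at the first and 57.4% at the last base, and G was 50.1% and 30.9%. In 5517 insertions of 2 bases, by contrast, A went from 39.7% to 32.3% and G from 49.7% to 48.1%. C was higher at the last than at the first base at each length, with 1.196% and 10.8% for 2 bases, 0.47% and 6.73% for 3, and 0% and 4.33% for 4. Insertions made only of A and G were 73.8% of those with 2 bases, 63.4% of those with 3 and 70.2% of those with 4. Where an inserted base equals its neighbour in the array its position is not unique, and these shares follow the positions in the deposited list. The base after the cut is C at the 6 sites ending in CGA and the 3 ending in CTA. An insertion starting with C there can equally be listed as one ending in C. The C shares by position can therefore come from the notation and do not show a change in composition. For A and G the effect of the notation was not tested, so their shares by position do not show a change in composition either. Events that recur in several alleles were counted in each, and their independence was not tested.

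Many longer inserted stretches matched the array's reverse complement. Of 2469 deletions with 8 or more inserted bases, 48.8% carried an insert found whole in the array's reverse complement, against 0.162% after shuffling the bases of each insert, and 6.24% an insert found whole in the array itself. Alleles with 6 or more events held a reverse-complement run in 43.5% of cases, and alleles with 2 to 4 events in 4.44%. The list gives such a run as several events, so a run itself can raise the number of events.

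Unedited and lightly edited arrays were missing from the list. The fewest altered sites in an allele was 3, and 25 alleles with 34 UMIs had 5 or fewer. A candidate explanation is that molecules above a length limit were lost in amplification, sequencing or allele calling. The test asked for a fall of at least 10-fold between neighbouring 10-base bins above the median length, and the largest fall was 15.1-fold, from 170 to 179 into 180 to 189 bases. In 27-base windows, which follow the repeat, alleles fell 2.22-fold and 2.69-fold over the 2 steps before and 21.1-fold from 464 alleles of 156 to 182 bases to 22 alleles of 183 to 209 bases. That the unedited entry alone was left out of a partly edited library stayed open: UMIs with 1 or 2 altered sites were 0% of UMIs, but a length limit would remove those too. No explanation resting on stage, lobe or animal was tested, since 1 library gives no groups.

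A few deletions between sites 1 and 10 were the most abundant alleles, and the exact cut-to-cut deletion was not among them, with 33 UMIs against 1589 for the largest allele. A candidate explanation is that exact joining of sites that end in the same 3 bases restores a target that can be cut again. Sites 1, 2, 3, 7, 8 and 10 end in CGA, sites 4, 5 and 6 in CTA and site 9 in ATA. Exact cut-to-cut deletions made up 5.998% ± 5.08 (SD, n = 18 site pairs) of deletions without inserted bases between sites with the same end and 37.8% ± 18.8 (SD, n = 27 site pairs) between sites with different ends. The difference of -31.8 percentage points had a permutation p of 1e-05 over pairs, the smallest possible. The permutation p was 0.0016 when the ends were reassigned among the 10 sites. Single pairs overlapped: with the same end they ran from 1.12% (sites 3 and 7) to 16.1% (5 and 6), and with different ends from 0% (3 and 4) to 78.9% (5 and 7). These shares count deletions over alleles and not UMIs. Between sites 1 and 10, 1 of 47 such deletions was exact. Such a deletion takes all 10 sites, so each product can hardly be listed in more than 1 allele. The share for this pair therefore says nothing on renewed cutting, though the pair entered the mean for the same end. Bases shared at the ends of a deletion stayed open as a source of the abundant products. Within equal lengths, the slope of log2(UMIs + 1) per shared base was 0.59 (permutation p = 0.274, 63 products, of which 31 were not listed and entered at 0 UMIs). It was 0.40 without the largest product (permutation p = 0.536) and 0.52 without the exact cut-to-cut product, which shares 8 bases (permutation p = 0.558). Of the products, 18 shared any base. The largest allele shares 3 bases, and with it the 2 products sharing 3 bases held 1596 UMIs. The 45 products sharing none held 1461 UMIs with a median of 0, and the 3 sharing 2 bases held 2. The bound written beforehand counted a p of 0.05 or more against this explanation; it was set aside after the result, since so few products with shared bases leave a positive slope neither shown nor excluded.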
